A study of Homo sapiens with 6 samples.

How the data were processed

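The data were 6 Affymetrix U133A arrays of MCF7 breast cancer cells, 3 labelled vector control and 3 labelled XBP1 by their titles. Per the labels' protocols, the cells were grown with 5% fetal bovine serum and 200 µg/ml Geneticin, RNA was extracted with Trizol and cleaned on a column, and it was labelled with biotin by a one-cycle reaction. Spike-in controls were included in each hybridisation and RNA quality was assessed by electrophoresis, per the design text.

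The authors deposited 1 summarised value per probe set and array on a log2 scale. The submitters' processing notes name MAS5 and RMA without saying which of them made these values or giving versions. The deposited log2 values were taken as RMA-like from their distribution: none was zero or negative, the array medians lay between 5.40 and 5.45, and no decile differed between arrays by more than 0.095. MAS5 values would usually have a wider scatter at the low end. The log2 values were used as deposited, with quantile normalisation as an alternative. RMA, if used, fits probe effects over the arrays together, so that values of different arrays are not wholly independent, and it compresses differences of dim probe sets; no detection call was used here. A log2 difference of 1 is a 2-fold difference on this scale.

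Of 22283 probe sets, 68 controls were left out of the tests and 22215 were tested. Gene names came from the platform annotation, which can be old, and were compared with a RefSeq gene table of assembly GRCh38.p14 through Entrez identifiers. That table was used only for names and for the order of neighbouring genes. 19065 probe sets had 1 gene, 1043 several and 2107 none; 19053 of those with 1 gene matched the table, and 0 symbols changed. Probe sets with several genes or none were tested and left unnamed. For each of 11963 genes the probe set with the highest mean over all 6 arrays was used, a choice that ignores the groups. Of 4310 genes with several probe sets, 2086 had probe sets whose differences disagreed in sign.

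The arrays labelled XBP1 were compared with the vector control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, no covariate and no filter on dim probe sets. P-values were adjusted by the Benjamini-Hochberg method over all probe sets or all genes, and differences were called at an adjusted p under 0.05. Standard errors and 95% intervals are those of the moderated fit. XBP1 and the control transcripts were also tested by a two-sided exact permutation test, which for 3 arrays against 3 has 10 distinct splits and a smallest p of 0.1.

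The comparison, its alternatives, the rule for naming genes and 31 gene lists were fixed before the data were examined. The rule names XBP1 first; then, among called genes whose groups do not overlap and whose brighter group mean lies above the 40th percentile, the 10 largest positive and 10 largest negative differences; then up to 3 called members of each list; and always ESR1, BCL2, PGR, HSPA5, DNAJB9 and CCND1. Where fewer than 10 genes were called in a direction, all were named and the rest of the 10 were taken by the smallest unadjusted p and given as values only. Members adjusted over the list alone, members given as examples of a list and genes named in the closing section fall outside this rule and were chosen after their values were seen.

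The lists held 781 entries, of which 683 were measured, and covered the unfolded protein response (targets of spliced XBP1, ATF6 targets, the PERK-ATF4 integrated stress response), the secretory pathway (COPII, COPI and Golgi trafficking, N-glycosylation), lipids (phospholipid and fatty acid synthesis, cholesterol synthesis), oestrogen response (induced genes, repressed genes, the receptor and its regulators), growth factor receptors and signalling, proliferation (S phase and mitotic cell cycle; cyclins D, CDK inhibitors and RB), death and survival (BCL2 family, caspases and death receptors, autophagy and lysosome), stress and immune programmes (interferon response, NF-kB targets, NRF2 and oxidative stress, hypoxia and glycolysis, cytosolic heat shock, immediate early genes), housekeeping machines (oxidative phosphorylation, cytosolic ribosomal proteins, proteasome subunits), S100 proteins, and markers of luminal, basal and myoepithelial, mesenchymal, leukocyte, and endothelial and adipocyte cells. They were written from general knowledge and not from these arrays. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with adjustment over the 31 lists. Camera with an estimated correlation and limma's fry, whose directional and mixed tests ask whether the genes of a list move without comparing them with other genes, were run beside it. With an estimated correlation, camera tests on the 4 residual degrees of freedom of the fit and not on the number of genes. Its calls are therefore harder to reach. Members were also adjusted over the list alone.

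The 3′ bias of each array was the mean over ACTB, GAPDH and the poly-A spike-ins dap, thr, phe and lys of the 3′ minus the 5′ probe set value. Alternatives were quantile normalisation, median centring, leaving out probe sets under the 40th percentile, trended and robust variances, no variance moderation, array weights, the replicate number as a block and as a covariate, the arrays numbered 2 and 6 alone, leaving out each array in turn, the mean of a gene's probe sets, leaving out probe sets with names ending in _x_at or _s_at, a 2-fold minimum and the other set tests. The 3′ bias as a covariate and the alternatives for the control transcripts were added after the data were seen. Pseudocounts were not varied, because the values already were on a log scale.

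The fits were tested on simulated arrays made from the means and spreads of the 11963 genes, in 20 runs with 50 genes changed at each of 4 sizes. At an adjusted p under 0.05 the limma fit recovered 23.0% of genes changed by 0.5 on the log2 scale, 70.5% at 1, 89.8% at 1.5 and 96.1% at 2, with a mean of 6.30 false calls per run. Camera called a list of 30 genes shifted by 0.25 in 20 of 20 runs and 0 of 600 unchanged lists, while the mixed test of fry called 34 of 600 unchanged lists. The simulated genes were independent of each other, so this does not test the preset correlation. Each gene's spread over these arrays, on 4 residual degrees of freedom, was taken as its true spread. The number of changed genes was also set in advance. The shares recovered may therefore be too high for the real arrays. No pair of arrays shared more than 0.103% identical values, and all 6 were used as separate samples.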

Results

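Gene expression was measured on 6 Affymetrix U133A arrays of MCF7, an established human breast cancer cell line of luminal epithelial type that expresses the oestrogen receptor. 3 arrays came from cultures labelled vector control (replicates 1, 2 and 6) and 3 from cultures labelled XBP1 (replicates 2, 3 and 6), all grown with 5% fetal bovine serum and 200 µg/ml Geneticin. These replicate numbers are those after p. in the titles, and whether p. stands for passage or preparation is not known. The numbers differ between the groups, so an effect of what they stand for was not balanced. XBP1 is a transcription factor of the unfolded protein response, the programme by which cells adjust to misfolded protein in the endoplasmic reticulum (ER), and is itself an oestrogen-induced gene. The title of the series places the comparison in the question of whether XBP1 frees breast cancer cells from oestrogen and protects them from antioestrogens; cells treated with antioestrogens were not analysed here. The design text describes the 6 cultures as grown on different days from different stocks, while the labels name 1 line per group. The p-values therefore measure the spread between these cultures and say nothing about other lines made with the same vectors. The deposited log2 values ran from 2.37 to 14.16 with medians of 5.40 to 5.45 per array. Across probe sets, which are not independent replicates, Pearson's r was 0.985 to 0.994 between arrays of one group and 0.974 to 0.992 between arrays of different groups. Their number of 3 per group limits the precision.

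XBP1 itself, measured by 1 probe set, was not higher in the arrays labelled XBP1. Its mean log2 value was 9.97 ± 0.12 (SD, n = 3) in the vector control and 9.81 ± 0.28 (SD, n = 3) in the arrays labelled XBP1. The difference was −0.16 with a standard error of 0.16 and a 95% confidence interval of −0.52 to 0.20 (limma, adjusted p = 0.781). A two-sided exact permutation test gave p = 0.4, where the smallest p that 3 arrays against 3 can give is 0.1. Where this probe set lies relative to the introduced cDNA was not examined, so its value checks the labels only if the cDNA contains the probed sequence. Groups are therefore called by their labels, and every direction below is that of the arrays labelled XBP1 relative to the vector control.

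Among 11963 genes, 17 differed between the groups at an adjusted p under 0.05, 9 higher and 8 lower in the arrays labelled XBP1. The largest fall was in SLC6A14, a plasma membrane transporter of neutral and cationic amino acids, which fell by 4.17 on the log2 scale (standard error 0.42, adjusted p = 0.0218), from 7.25 ± 0.98 to 3.08 ± 0.15 (SD, n = 3 each). The lower mean lay at the 5.60th percentile of all probe sets, so the 18.0-fold difference depends on the floor of the array. With the 3′ bias of the arrays as a covariate the SLC6A14 difference was −2.66 (standard error 0.54) and that of PALLD, at −3.19 (standard error 0.47), was the largest of the 8; neither passed in that fit. PALLD, which encodes the actin-bundling protein palladin, fell by 2.70 (6.51-fold, standard error 0.25), and all of its 3 probe sets were lower. ATP8A2, a phospholipid flippase, fell by 2.08, RAB31, a GTPase of vesicle traffic, fell by 1.87, and TM4SF1, a membrane protein of the tetraspanin-like L6 family, fell by 1.46. GPRC5A, an orphan receptor induced by retinoic acid, fell by 1.20, LOXL2, a lysyl oxidase that cross-links collagen, fell by 1.19, and RPRM, a mediator of arrest in G2, fell by 1.06. One of the 3 LOXL2 probe sets differed by 0.08 in the other direction, and the mean over its probe sets differed by −0.37 (adjusted p = 0.364).

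The 9 genes that rose were led by SGCE, the epsilon member of the sarcoglycans, with a log2 difference of 1.96 (3.89-fold, standard error 0.19, adjusted p = 0.0169). It went from 3.97 ± 0.20 to 5.93 ± 0.34 (SD, n = 3 each). The lower means of SGCE and LOXL2 lay at the 20.5th and 26.8th percentiles of all probe sets, so their folds depend on the floor of the array as well. FAR2, which reduces fatty acyl-CoA to fatty alcohol, rose by 1.69, PODXL, the sialomucin podocalyxin, by 1.56, and PPT1, a lysosomal enzyme that removes palmitate from proteins, by 1.36. SLC3A2, the heavy chain of the amino acid transporter CD98, rose by 1.57 (2.98-fold, standard error 0.17, adjusted p = 0.0223). ASNSD1 (1.25), POLE3, a subunit of DNA polymerase epsilon (1.02), the kinase DYRK4 (0.91) and RMND1, a protein of mitochondrial translation (0.81), also rose. The adjusted p-values of all 17 genes were between 0.0169 and 0.0493. Next in line by p were CACNA1D, an L-type calcium channel, with a log2 difference of 1.29 (adjusted p = 0.0506), TANC2 with −0.97 (adjusted p = 0.0506) and PHLDA2 with −0.86 (adjusted p = 0.0569; −0.05 in its other probe set), none of which passed the test.

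**Figure D1:**
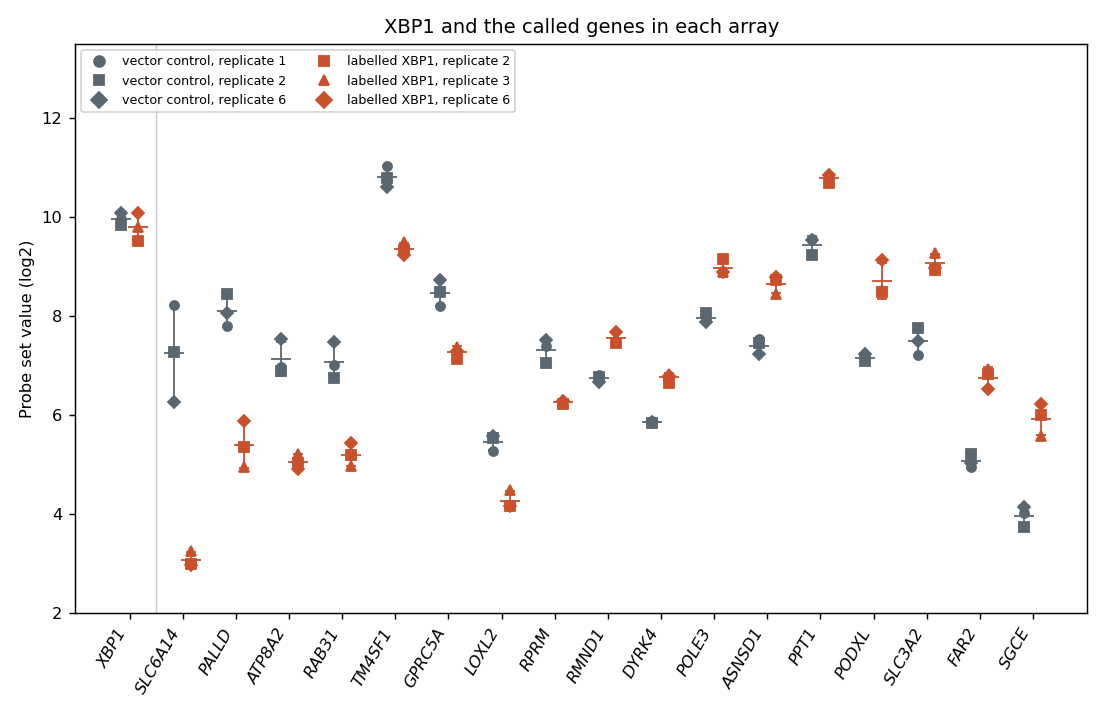
Log2 probe set value (vertical axis) of XBP1, left of the line, and of the 17 genes that passed the test, ordered by their difference, in each of the 6 arrays. Symbols show the replicate, grey the vector control, orange the arrays labelled XBP1, and bars the mean ± SD of 3 arrays; the groups overlap for XBP1 and do not overlap for any of the 17 genes.

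For all 17 genes the 3 arrays of one group lay above the 3 of the other, as did 16.01% of all genes, where unrelated groups would give 10%. At an unadjusted p under 0.05 there were 1310 genes, or 10.95% of those tested, and the median log2 difference over all genes was −0.0048. At the level of single probe sets, 29 of 22215 differed, 13 higher and 16 lower. They name 19 genes, the 17 above and, chosen after their values were seen, KYNU (1.28) and FGFR4 (0.77), which passed by a probe set other than the brightest (the 4 KYNU probe sets ranged from −0.0045 to 1.28); 4 of the 29 had no single gene name. The counts moved with each array left out: without vector control replicate 1, 2 or 6 limma called 0, 0 and 2 genes (824, 932 and 1450 at an unadjusted p under 0.05), and without XBP1 replicate 2, 3 or 6 it called 33, 9 and 4, of which 13, 8 and 3 were among the 17. Without limma's pooling of variances 0 genes passed (1068 at an unadjusted p under 0.05), with the arrays numbered 2 and 6 alone 0 (1124) and with the 3′ bias of the arrays as a covariate 0 (327). All 17 kept their direction in these fits. As their groups do not overlap, only the fit with the 3′ bias could have turned it. That 3′ bias, averaged over 6 control transcripts, was itself lower in the arrays labelled XBP1 (1.09 ± 0.01 against 1.61 ± 0.28, SD, n = 3 each).

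Genes of the oestrogen response differed in both directions. Of 41 measured oestrogen-induced genes, 1 (RAB31) fell and 0 rose over all genes tested, and 9 were higher and 5 lower adjusted over the list alone. Those higher were the amino acid transporter SLC7A5 (1.56), the secretory protein AGR2 (1.48), the receptor tyrosine kinase RET (0.97), HSPB8 (0.93), the progesterone receptor PGR (0.91), MYC (0.66), BCL2 (0.61), IL17RB (0.60) and SIAH2 (0.55). Those lower were RAB31 (−1.87), the carbonic anhydrase CA12 (−1.60), EGR3 (−0.86), the receptor corepressor NRIP1 (−0.82) and PDZK1 (−0.56). The 6 CA12 probe sets ranged from −1.60 to 0.02. The list had no direction as a whole, with a median of −0.01, a mean of 0.11 and an adjusted p of 0.711 by limma's camera, a test against the other genes. Its fry test for change in either direction gave an adjusted p of 5.68e-04. That test called 12 of the 31 lists here, and in simulated data it called 34 of 600 unchanged lists, so it is weak evidence.

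ESR1, the oestrogen receptor itself, had a log2 difference of 0.70 (standard error 0.18, adjusted p = 0.203 over all genes by limma), and its 9 probe sets ranged from −0.12 to 0.70. PGR differed by 0.91 (adjusted p = 0.277) and the survival gene BCL2 by 0.61 (adjusted p = 0.245), with the 4 BCL2 probe sets between −0.08 and 0.61. PGR was dim, with its vector control mean at the 38.6th percentile of all probe sets. All 3 genes were higher in each array labelled XBP1 than in any vector control array, and none passed the test over all genes. CCND1, the cyclin of G1 entry, differed by −0.23 (adjusted p = 0.726). In the list of the oestrogen receptor and its regulators (17 genes), ESR1 was higher and NRIP1 lower adjusted over the list alone, 0 passed over all genes, and camera gave an adjusted p of 0.771 with a median of −0.02. Among 21 oestrogen-repressed genes, 0 passed over all genes; adjusted over the list alone CYP1B1 (1.25) and EFEMP1 (1.15) were higher and BMP7 (−1.63) lower, with a median of 0.17 and an adjusted p of 0.215.

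Targets of the unfolded protein response had differences of both signs. Of 39 measured targets of spliced XBP1 in ER folding and ER-associated degradation, 18 had positive and 21 negative differences, and 0 passed over all genes. Adjusted over the list alone, RPN1 of the oligosaccharyltransferase was higher (0.81) and DERL2 (−0.79) and SDF2L1 (−0.54) were lower, both of them proteins of ER quality control. The mean log2 difference of the list was 0.02 (95% confidence interval over genes, which are not independent, −0.09 to 0.14), its median −0.01 and its camera adjusted p 0.774. The chaperone HSPA5 differed by −0.04 (standard error 0.16, adjusted p = 0.960) and its cofactor DNAJB9 by −0.27 (standard error 0.24, adjusted p = 0.745). For the 13 ATF6 targets the median was −0.15, with SDF2L1 lower adjusted over the list alone, 0 over all genes and an adjusted p of 0.660. The direction of the spliced XBP1 list turned under quantile normalisation, and those of HSPA5 and DNAJB9 turned in several other settings.

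Genes of the integrated stress response, among them amino acid transporters, were called upward by camera with its preset correlation (adjusted p = 0.00912) and not with an estimated correlation (adjusted p = 0.608). With an estimated correlation camera has 4 degrees of freedom, and its lowest unadjusted p over all 31 lists was 0.055. A call lost there, for this list or those below, can reflect that limit as well as the correlation. Of 28 measured genes of the PERK-ATF4 branch, SLC3A2 rose over all genes, and SLC3A2 and SLC7A5 were higher adjusted over the list alone. SLC7A5, the light chain that pairs with SLC3A2 to form a leucine transporter, went from 9.50 ± 0.43 to 11.06 ± 0.18 (SD, n = 3 each) with an adjusted p of 0.0569 by limma over all genes. 18 members had positive and 10 negative differences, with a median of 0.06. The 3′ bias of the arrays differed beside it (1.09 against 1.61), and with the bias as a covariate the adjusted p was 0.207. Among single arrays, the call was lost without vector control replicate 6 (adjusted p = 0.128) or XBP1 replicate 6 (adjusted p = 0.157), and it was lost with array weights (adjusted p = 0.0612), over a range of 0.00115 to 0.662 in all settings.

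Lists of the secretory pathway and of cholesterol synthesis were called upward, with medians of 0.13 to 0.20. All 3 calls were lost with an estimated correlation (adjusted p = 0.608 each). For 29 N-glycosylation genes 25 differences were positive, with a median of 0.20 and an adjusted p of 0.00287 (camera, preset correlation). Its largest positive members by p were RPN1 (0.81), ALG9 (0.45) and ALG3 (0.49), while MAGT1 differed by −0.75 (0.16 in its other probe set); 0 members passed adjusted over the list alone or over all genes, and 4 positive and 1 negative had an unadjusted p under 0.05. For 32 genes of COPII, COPI and Golgi trafficking the median was 0.13 and the adjusted p 0.0457, and COPG1 (0.85) alone was higher adjusted over the list alone, with 0 over all genes. For 17 cholesterol synthesis genes the median was 0.16 and the adjusted p 0.00628, and the largest differences were those of TM7SF2 (0.84) and PMVK (0.79), with 0 members passing adjusted over the list alone or over all genes and 5 at an unadjusted p under 0.05. Phospholipid and fatty acid synthesis, with 17 genes, had a median of −0.10, an adjusted p of 0.869 and 0 members passing adjusted over the list alone or over all genes, with 1 at an unadjusted p under 0.05. With the 3′ bias of the arrays (1.09 against 1.61) as a covariate, the adjusted p was 0.347 for N-glycosylation, 0.207 for trafficking and 0.654 for cholesterol synthesis. The trafficking call ended without vector control replicate 2 (0.0969), vector control replicate 6 (0.0567) or XBP1 replicate 6 (0.659), without dim probe sets (0.0615), with trended and robust variances (0.0634) and with the mean of a gene's probe sets (0.0847), over a range of 0.00389 to 0.659, and the cholesterol call without XBP1 replicate 2 (0.0572).

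Oxidative phosphorylation, luminal epithelial markers and S100 proteins were each called upward with an adjusted p of 0.00287 (camera, preset correlation), and all 3 calls were lost with an estimated correlation (adjusted p = 0.608 each). For 33 genes of oxidative phosphorylation the median was 0.13, and ATP5F1B, the catalytic beta subunit of ATP synthase (0.64), was higher adjusted over the list alone, with 0 over all genes. For 20 luminal markers the median was 0.34, and AGR2 (1.48), MUC1 (1.30), KRT8 (0.90) and ESR1 (0.70) were higher adjusted over the list alone, with 0 over all genes, while GATA3 differed by −0.49. Relative to the vector control mean, the luminal list stood at 0.156, 0.45 and 0.632 in XBP1 replicates 2, 3 and 6. Vector control replicate 6, at 0.204, lay above XBP1 replicate 2. For 14 S100 proteins, a family of small calcium-binding proteins, the median was 0.24 and the mean 0.51, and S100A4 (2.11), S100A6 (1.31), S100A8 (0.99) and S100A13 (0.85) were higher adjusted over the list alone, with 0 over all genes; the other probe set of S100A8 differed by −0.11 and that of S100A13 by −0.17. With the 3′ bias of the arrays (1.09 against 1.61) as a covariate, the adjusted p was 0.00454 for oxidative phosphorylation and 0.207 for each of the other lists. Without XBP1 replicate 2 the oxidative phosphorylation call ended (0.102), and without XBP1 replicate 6 the luminal call did (0.0626).

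Hypoxia and glycolysis genes were called upward with an adjusted p of 0.0479 over 28 genes with the preset correlation and not with an estimated correlation (adjusted p = 0.997). The median was 0.19, with 0 members passing adjusted over the list alone or over all genes (2 positive and 1 negative at an unadjusted p under 0.05). The shift lay in one array: relative to the vector control mean, the list stood at 0.60 in XBP1 replicate 6 and at −0.075 and 0.001 in XBP1 replicates 2 and 3, while vector control replicate 6 stood at 0.26. Without XBP1 replicate 6 the direction turned (adjusted p = 0.851), and without vector control replicate 1 or 2 the call ended (0.178 and 0.370). It also ended with median centring (0.0713), without dim probe sets (0.165), with the replicate number as a covariate (0.166), with the mean of a gene's probe sets (0.0905) and with the 3′ bias of the arrays as a covariate (0.668). Of the 8 calls, quantile normalisation left 3 (N-glycosylation, luminal markers and S100 proteins), and leaving out probe sets ending in _x_at or _s_at left 1 (oxidative phosphorylation). The latter step also removed some genes and measured others by another probe set, so the lists were not the same.

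**Figure D2:**
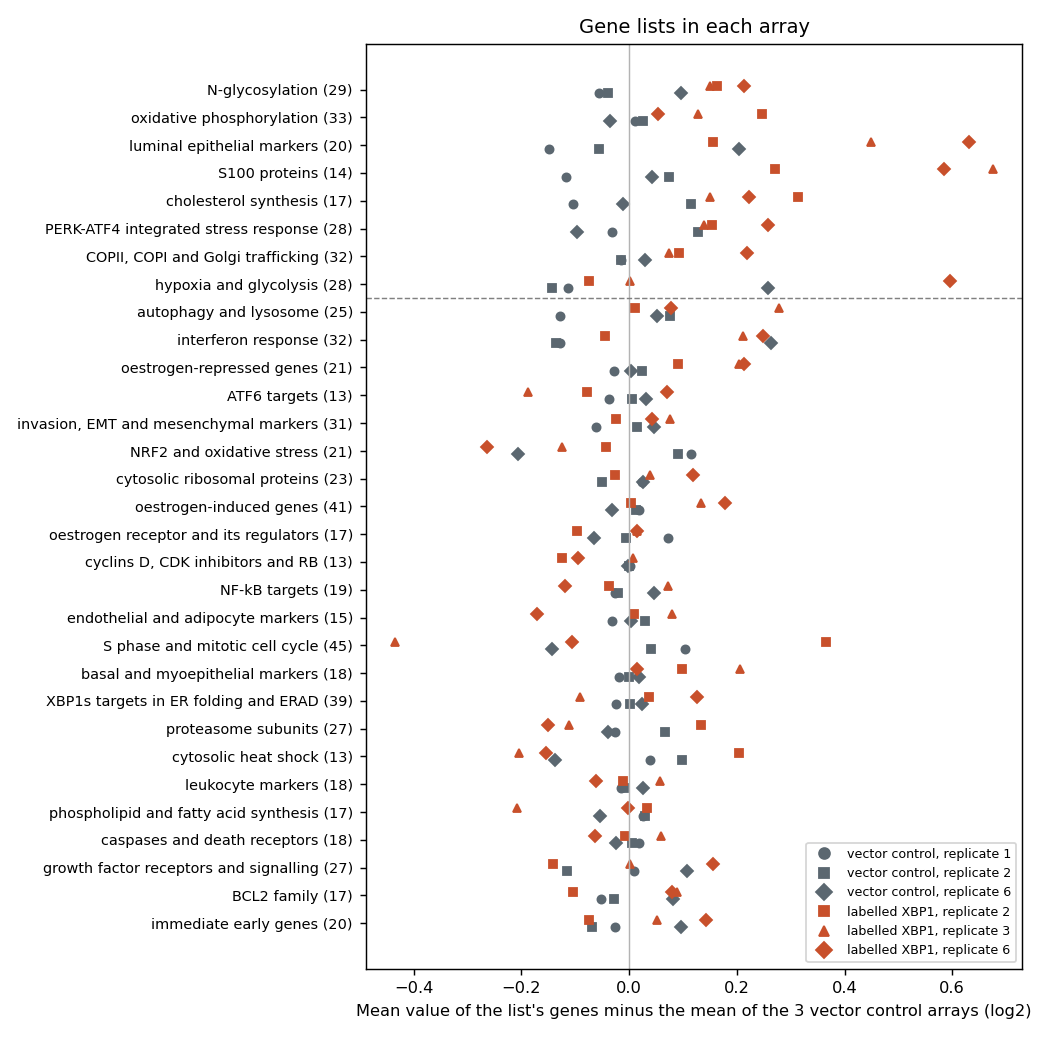
Mean log2 value of the measured genes of each of 31 lists (number of genes in parentheses) minus the mean of the 3 vector control arrays, for each array, with lists ordered by the p of the camera test. Grey symbols are vector control arrays, orange symbols the arrays labelled XBP1, and the 8 lists above the dashed line were called with the preset correlation and lost their call with an estimated one; the hypoxia shift is that of XBP1 replicate 6 (0.60).

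Markers of other cell types gave no call. For 18 basal and myoepithelial markers the median was −0.02, the mean 0.11 and the adjusted p 0.774, with the keratin KRT15 (1.08) higher adjusted over the list alone and 0 over all genes. KRT15 went from 3.52 in the vector control to 4.61, both below every array median (5.40 to 5.45). Its difference therefore depends on the floor of the array. For 31 invasion, EMT and mesenchymal markers the median was 0.06 and the adjusted p 0.661, for 18 leukocyte markers 0.0013 and 0.866, and for 15 endothelial and adipocyte markers −0.04 and 0.774, with 0 members passing adjusted over the list alone or over all genes in these 3 lists and 2, 0 and 0 at an unadjusted p under 0.05.

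Proliferation and cell death genes gave no call. The 45 genes of S phase and mitosis stood at 0.37 in XBP1 replicate 2, at −0.43 in XBP1 replicate 3 and at −0.11 in XBP1 replicate 6 relative to the vector control mean, with a median of −0.04 and an adjusted p of 0.774. Cyclins D, CDK inhibitors and RB (13 genes) had a median of −0.02 and an adjusted p of 0.771. In both lists 0 members passed adjusted over the list alone or over all genes, with 3 and 0 at an unadjusted p under 0.05. In the BCL2 family (17 genes), BCL2 (0.61) was higher and PMAIP1 (−0.77) and BID (−0.53), both promoters of cell death, were lower adjusted over the list alone, with 0 over all genes, a median of −0.0035 and an adjusted p of 0.997. Caspases and death receptors (18 genes) had a median of 0.01, an adjusted p of 0.993 and 0 members passing either adjustment, with 1 positive and 1 negative at an unadjusted p under 0.05. Among growth factor receptors and signalling genes (27 genes, median −0.08, adjusted p 0.997), RET (0.97) and FGFR4 (0.73) were higher and GFRA1 (−0.82), a coreceptor of RET, was lower adjusted over the list alone, with 0 over all genes. Immediate early genes (20 genes, median 0.02, adjusted p 0.997) held 1 member higher (MYC) and 2 lower (EGR3 and KLF6) adjusted over the list alone, and 0 over all genes.

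The remaining lists were not called either. Autophagy and lysosome genes (25 genes) had a median of 0.13 and an adjusted p of 0.0990, with the autophagy gene BECN1 (0.70) higher adjusted over the list alone. NRF2 and oxidative stress genes (21 genes) had a median of −0.03 and an adjusted p of 0.661, with the exporter ABCC3 (−1.12) lower adjusted over the list alone. Interferon response genes (32 genes) had a median of 0.18 and an adjusted p of 0.162, NF-kB targets (19 genes) −0.03 and 0.771, and cytosolic ribosomal proteins (23 genes) 0.06 and 0.661. Proteasome subunits (27 genes) had a median of −0.05 and an adjusted p of 0.836, and cytosolic heat shock genes (13 genes) −0.03 and 0.836. In these last 5 lists 0 members passed adjusted over the list alone, with 1, 0, 1, 3 and 0 at an unadjusted p under 0.05, and in all 7 lists 0 passed over all genes. Median and mean had opposite signs for the oestrogen-induced, spliced XBP1, basal, leukocyte, caspase, growth factor and BCL2 lists. For the oestrogen-induced, spliced XBP1, basal and leukocyte lists camera had the sign of the mean and for the caspase list that of the median. The camera direction was down for the growth factor and BCL2 lists, whose means were 0.01 and 0.02, and down for the leukocyte list, whose median was 0.0013. The fry direction was up for the growth factor list and down for the immediate early list, the reverse of camera.

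Control transcripts differed between the groups in the balance of their 3′ and 5′ probe sets. For beta-actin (ACTB), the 3′ minus 5′ log2 difference was 1.97 ± 0.73 (SD, n = 3) in the vector control and 0.58 ± 0.05 (SD, n = 3) in the arrays labelled XBP1. For the bacterial poly-A transcripts added to the RNA it was 2.04 against 1.45 for dap, 1.61 against 1.00 for thr, 1.73 against 1.54 for phe and 2.03 against 1.88 for lys. The groups were fully separated for ACTB, dap, thr and phe (two-sided exact permutation p = 0.1 each, the smallest possible), and not for lys (exact p = 0.6) or GAPDH (0.26 against 0.08, exact p = 0.2). The mean over these 6 transcripts, the 3′ bias of an array, was 1.61 ± 0.28 (SD, n = 3) in the vector control and 1.09 ± 0.01 (SD, n = 3) in the arrays labelled XBP1. Every gene and list difference above was therefore measured between groups of arrays that also differed in 3′ bias. Of 9 probe sets for hybridisation controls, which are added after labelling, 0 separated the groups.

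**Figure D3:**
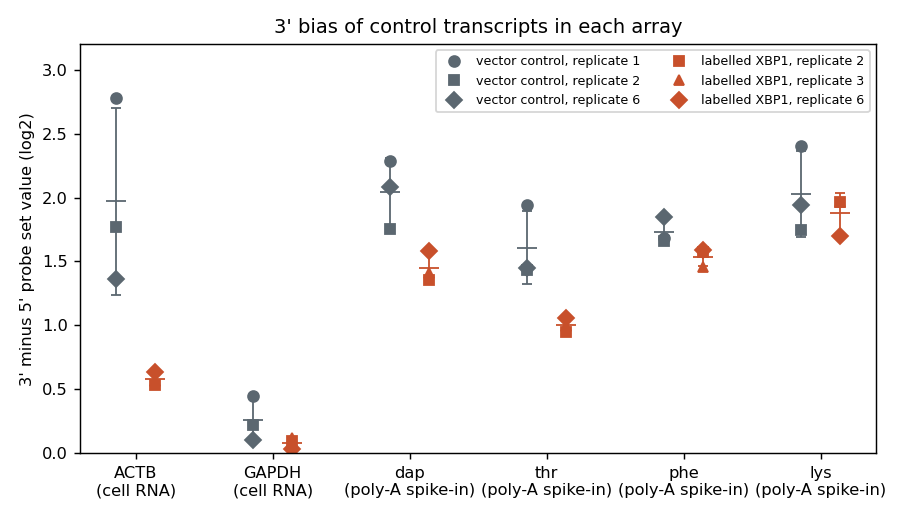
The 3′ minus 5′ log2 difference (vertical axis) of 2 cell transcripts and 4 poly-A spike-in transcripts in each of the 6 arrays, with bars for the mean ± SD of 3 arrays per group. Grey symbols are vector control arrays and orange symbols the arrays labelled XBP1, which lie below all vector control arrays for ACTB, dap, thr and phe.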

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

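All tests below were chosen after the results were seen, except that of differences between sublines; the test of the 3′ bias as a continuous effect was added after the data were seen.

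Control probe sets, which took no part in the comparisons, held 6 signals that were higher in each array labelled XBP1 than in any vector control array, with mean log2 differences of over 0.5. They were the 5′ (log2 difference 1.44) and middle (0.758) probe sets of ACTB and the 5′ probe sets of the spike-ins dap (0.730 and 0.664) and thr (0.697 and 0.581). Of 68 control probe sets, 8 were higher, these 6 among them, and 5 lower in all 3 arrays labelled XBP1 whatever the size, where unrelated groups would give 5% each way. Among all 22215 tested probe sets, 15.69% separated the groups in either direction, so separation was not particular to the controls. Degradation of the cells' own RNA alone would leave exogenous transcripts unchanged, while dap and thr (2 of 2) separated the groups in 3′ minus 5′. These 2 were taken because their 5′ signals had been flagged, so their separation was nearly given and does not decide this. Of the spike-ins not flagged, phe separated the groups and lys did not (exact permutation p = 0.6). A larger amount of spike-in RNA is argued against, since the 3′ probe sets of dap and thr rose by 0.0803 on average and their 5′ probe sets by 0.681. A difference in the labelling reaction, which would shorten cell and spike-in transcripts alike, stays a candidate that these values do not decide. In 3′ minus 5′, 3 of the 4 poly-A spike-ins separated the groups and 0 of 9 hybridisation controls did. However, 2 of these 3 were the flagged dap and thr. The third, phe, separated through a lower 3′ value (−0.18), with little difference at 5′ (0.01), and lys did not separate. Among cell transcripts, GAPDH did not separate the groups either (exact permutation p = 0.2). No biological explanation was tested.

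The 17 genes and 29 probe sets that differed between the groups could come from XBP1, from the line or from the handling of the arrays. The real split was 1 of 10 for genes and 1 of 10 for probe sets to reach its count, with at most 0 of either in the other splits, and 10 splits are too few for a share under 0.05. Since 4 of 6 control transcripts separated the groups, a labelling batch that coincides with the groups cannot be told apart from them, and the same holds for differences between the lines other than XBP1, because the labels name 1 line per group. As a continuous effect, the 3′ bias predicted a median share of −0.0387 of the differences of the 17 genes (quartiles −0.157 and 0.123), and with the bias as a covariate all 17 kept their direction while the calls ended as the median standard error widened from 0.14 to 0.26 (median absolute log2 difference 1.46 before and 1.51 after). This stays open too, because without vector control replicate 1 the bias varied within groups by at most 0.0340, against 0.518 between them.

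The XBP1 probe set, with a log2 difference of −0.16, was not higher in the arrays labelled XBP1. With 1 named probe set for the gene, it cannot be told whether the probed sequence lies outside the introduced cDNA, in which case the signal would be that of the cells' own gene. If introduced XBP1 acted on its target genes, those of ER folding and degradation would be higher; their median log2 difference was −0.0125 and the 95% interval of their mean, −0.0929 to 0.139, leaves a small rise open. As the members differed in both directions, this does not decide the matter. A mistaken label was not tested.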

How the results depend on the processing

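Every alternative here was planned, except the 3′ bias as a covariate and those for the control transcripts, which were chosen after the data were seen. Over 18 alternatives the 17 called genes kept their direction in 299 of 299 values and passed in 163, and the XBP1 difference stayed between −0.30 and −0.02 without passing. Many of the alternatives, such as leaving out arrays or changing the variances, cannot turn a gene whose groups do not overlap. The kept direction was therefore largely given in advance. The counts moved more: trended and robust variances gave 60 probe sets and 29 genes, array weights 87 and 50, and the replicate number as a covariate 55 and 37. No moderation of variances gave 0 and 0 (1895 and 1068 at an unadjusted p under 0.05), the arrays numbered 2 and 6 alone 0 and 0 (2021 and 1124), and the 3′ bias as a covariate 0 and 0 (654 and 327), with 1 list. Leaving out probe sets ending in _x_at or _s_at gave 11 genes, since 11 of the 17 were still measured, and 1 list. Leaving out single arrays gave 1 to 43 probe sets, 0 to 33 genes and 4 to 9 lists. Lists called fell from 8 to 3 with quantile normalisation, 0 with an estimated correlation and 0 with fry (0 and 2 lists at an unadjusted p under 0.05); list tests were not run without moderation. The replicate block on the numbers shared by 2 pairs of arrays gave 1089 probe sets and 852 genes, with 1 residual degree of freedom, and kept all 29 and 17; ESR1 (0.61), BCL2 (0.63), PGR (0.72) and CCND1 (−0.46) passed in this fit alone. The pairing rests on a number alone, whose pairs of arrays had correlated deviations of 0.30 and 0.11. Over probe sets, the XBP1 minus vector control differences of the 2 same-numbered pairs correlated at 0.511. With the numbers swapped they correlated at 0.0673, so the number may mark a factor shared between the groups. Directions turned for HSPA5 with array weights (0.039), the replicate block (0.10), numbers 2 and 6 alone (0.10) and single arrays left out (−0.15 to 0.13, turning without vector control replicate 6 or XBP1 replicate 3), DNAJB9 with the block (0.085), numbers 2 and 6 alone (0.085) and the 3′ bias (0.26), and CCND1 without _x_at and _s_at probe sets (0.049), which uses another probe set. The spliced XBP1 list turned with quantile normalisation (adjusted p = 0.960), without those probe sets (0.989) and without XBP1 replicate 6 (0.851, single arrays left out 0.311 to 0.861), over a range of 0.271 to 0.997, and the hypoxia list, the only one of these that had passed, turned without XBP1 replicate 6 (0.851), over 0.00145 to 0.997. Unless stated, the cause was not tested. Of the gene and list values that did not turn, 431 kept direction and side of the threshold, 189 fell below it and 15 passed it. No detection call was used, so how far background limits the dim genes was not measured.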

Other observations

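The tests of neighbouring genes and of the oestrogen-induced list against random lists were chosen after the results were seen, and the genes named here were chosen after their values were seen.

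Some genes whose groups did not overlap had differences of over 2-fold and did not pass the test over all genes. Higher in every array labelled XBP1 were MSMB (log2 difference 2.30, adjusted p = 0.147 by limma), a protein of glandular secretions, CEACAM6 (2.05, 0.0676), a cell adhesion molecule, INHBB (1.90, 0.101), a subunit of activins and inhibins, and TNFRSF11B (1.37, 0.0596), the decoy receptor osteoprotegerin. Lower in every array labelled XBP1 were IGSF1 (−2.78, 0.0966), the growth factor BMP7 (−1.63, 0.0569), the protease inhibitor SERPINA3 (−1.57, 0.0587) and the cytidine deaminase APOBEC3B (−1.55, 0.114). CRABP2, which carries retinoic acid to its receptor, had a difference of −1.56 (adjusted p = 0.156) and CYP26B1, which degrades retinoic acid, one of 1.56 (adjusted p = 0.225).

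The list shifts of single cultures did not follow the groups for proliferation. S phase and mitotic genes were correlated with each other at 0.610 within groups, and their mean ranged from −0.43 in XBP1 replicate 3 to 0.37 in XBP1 replicate 2, while the vector control arrays lay between −0.14 and 0.10. The first principal component held 42.8% of the variance. On it vector control replicates 1, 2 and 6 stood at −31.1, −17 and −1.20, and XBP1 replicates 2, 3 and 6 at −0.700, 34.1 and 15.9. All vector control arrays thus lay below all arrays labelled XBP1, as unrelated groups would separate in 10% of cases. Vector control replicate 6 and XBP1 replicate 2 lay next to each other.

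Other groupings of the arrays called as many gene lists. Of the 10 splits of the 6 arrays, 3, the real split among them, called at least the 8 lists of the real split. The highest other count was 9, for vector control replicate 1 with XBP1 replicates 3 and 6 against the rest. With 10 splits no share under 0.05 can be reached. Genes of a list vary together between cultures whatever their group, which is a candidate explanation for the calls with the preset correlation.

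Whether oestrogen-induced genes differed between the groups more than other genes of like expression stays open. Against random lists of genes the list stood at the percentile 100 by its mean absolute moderated t, but it was chosen for its differences in the same arrays, so this test decides nothing. In other splits of the arrays the percentile reached 99.87.

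Copy number segments that differ between the lines are a candidate explanation for differences shared by neighbouring genes. Over 11932 genes in chromosome order, the differences of adjacent genes had a correlation of 0.114, above the highest of 200 shuffled orders (0.0230). Other splits gave 0.0401 to 0.198, and 3 of 9 lay above the real one, so neighbours also vary together between cultures and the test does not separate the lines.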
